A study of Mus musculus with 6 samples.

How the data were processed

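The series holds 6 RNA-seq libraries of mouse primary lung fibroblasts, 3 given PBS and 3 given recombinant mouse CIRBP. The authors deposited 1 table of raw counts per gene, with 1 column for each library. Per the labels' protocols, cells were grown in 10% serum, kept in 0.1% serum for 24 h and treated for 24 h, and libraries were made from polyA-selected RNA with a TruSeq mRNA kit. Per the submitters' processing notes, reads were assigned to genes of the GRCm38 (mm10) build with featureCounts, and DESeq2 and R 4.1.2 were used. The aligner, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Without a stated strand setting, reads of a gene and of its antisense partner cannot be told apart, and genes of families with shared sequence are uncertain. Columns were matched to samples by the group and number in their titles, leaving 0 unmapped.

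The table lists 55487 genes, 21936 of them protein coding, and 0 lines that name no gene. Of the gene identifiers, 55227 were found in a GENCODE annotation of GRCm38, and 54907 of these had the same start and end. Gene symbols, biotypes, coordinates and Gene Ontology terms are those of the deposited table. Depth was 12105584 to 14262375 counts per library, so that 3 counts, the limit that a count of 0 allows, correspond to 0.210 to 0.248 CPM. Such limits cover counting error only.

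Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group, leaving 15801, and scaled by trimmed mean of M values. The main test was edgeR's quasi-likelihood F test, two-sided, with an intercept and treatment and no other covariate, and Benjamini-Hochberg adjustment over the genes tested at 0.05. Standard errors of log2 fold changes were taken from the fold change and its F statistic. CPM values are given as mean ± SD over 3 libraries. Where a gene had no count in PBS, its fold change was given as a lower bound against 3 counts over the group.

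Gene lists were tested with camera from limma 3.58.1 on voom values with a preset correlation of 0.01 between genes, beside camera with an estimated correlation and fry. There were 20 pathway lists, adjusted as 1 family, and 9 cell type and 2 quality lists, adjusted as another, and lists with fewer than 5 tested members were not tested as sets. Of the listed symbols, 4 were not in the table. Terms with 10 to 500 tested genes were tested with camera, adjusted over all terms, the tested genes being the background. Principal components were computed on log2 CPM with a prior count of 2. Pairs of libraries were compared by chi-square over genes with at least 20 counts to look for duplicates. Group means of library measures were compared by exact permutation.

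The groups, the main tests, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except for the alternatives and tests that the closing section names as chosen after the results were seen. By that rule the text takes its genes from the 8 protein-coding genes with the largest called increase and the 8 with the largest decrease that had a mean of at least 1 CPM and groups that did not overlap, the genes named by the study's title and design, up to 3 members of each pathway list with the smallest p, up to 2 most abundant members of each cell type list, and the 3 genes with the smallest p. Other genes are named where a list had few changed members, and are marked as chosen after their values were seen.

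The scripts were tested on simulated counts for the 15801 genes of rmCIRBP against PBS, of which 200 were changed. edgeR recovered 58% of the genes changed 2-fold and 90% of those changed 4-fold, with 6.33% false among 158 calls. limma voom recovered 53% and 87% with 6.04% false, and DESeq2 1.42.0 recovered 74% and 96% with 17.5% false. Camera called 10 of 10 shifted lists and 0 of 40 others, and fry called 10 and 1. The simulated genes were drawn independently, so these rates do not cover lists whose genes move together.

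Alternatives were DESeq2 size factors, library size and upper quartile scaling, other filters on low counts, DESeq2, limma voom, a robust edgeR fit, the replicate number as a block, leaving out each library, other thresholds, protein-coding genes alone, and for lists other set tests.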

Results

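RNA was sequenced from primary lung fibroblasts of wild-type C57BL/6 mice that were starved of serum (0.1%) for 24 h and then kept for 24 h with PBS or with recombinant mouse cold-inducible RNA-binding protein (rmCIRBP) at 1 µg/mL. CIRBP is an RNA-binding protein induced by mild cold, and outside the cell it is known as a ligand of the Toll-like receptor TLR4. There were 3 libraries per group, from polyA-selected RNA, sequenced in 1 batch. The reads counted to genes numbered 12172622, 12105584 and 14262375 in the PBS libraries and 13677385, 13925054 and 14001478 in the rmCIRBP libraries. The group means gave a two-sided exact permutation p of 0.4 (n = 3 each), where 0.1 is the smallest that 3 against 3 allows. A count of 0 in a library allows up to 3 counts, which is 0.210 to 0.248 CPM (counts scaled to library size), and such limits cover counting error only. The labels do not say whether the replicates were separate animals or cultures, so the p-values measure the spread between these samples, which may be technical.

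The libraries separated by treatment. The first principal component of log2 CPM held 61.8% of the variance and parted the groups, with scores from -54.4 to -34.9 in PBS and from 42.1 to 53.5 in rmCIRBP. The second component held 18.0% and parted libraries within each group. PBS 1 scored 28.6 on it and rmCIRBP 2 scored 38.8, whereas rmCIRBP 3 scored -36.6. Actg2 and Myh11, which encode smooth muscle actin and myosin, were among the genes weighing most on the high side of this component. Pearson's r across genes, which are not independent replicates, was 0.964 to 0.984 within groups and 0.920 to 0.946 between them. No pair of libraries differed by as little as sampling noise, the smallest chi-square per degree of freedom being 14.2.

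**Figure D1:**
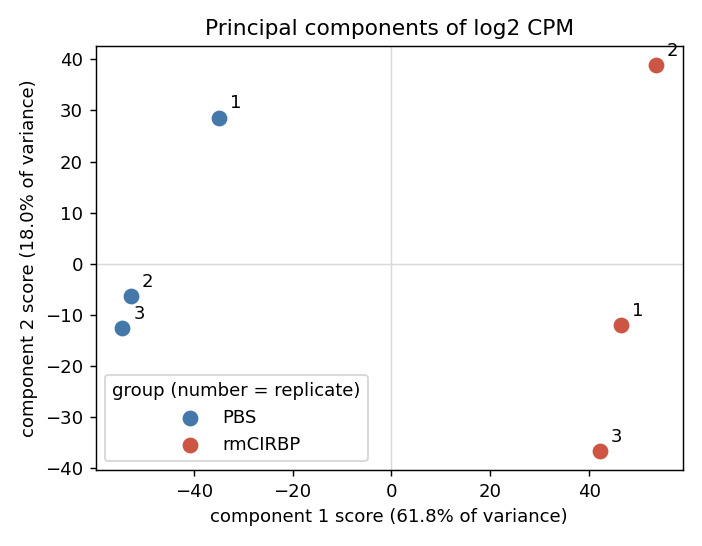
Scores of the 6 libraries on the first component (horizontal axis, 61.8% of the variance) and the second (vertical axis, 18.0%), without units, coloured by group and numbered by replicate. The groups separate along the first component, and PBS 1 and rmCIRBP 2 sit high on the second.

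The comparison of rmCIRBP with PBS asked what extracellular CIRBP does to the transcriptome of lung fibroblasts. Acute-phase and chemokine genes were among those that rose. Saa3, a serum amyloid A protein (chromosome 7, 46711998 to 46715700, GRCm38), rose from 0.160 ± 0.0906 CPM (SD, n = 3) to 1853 ± 370 CPM (SD, n = 3). Its log2 fold change was 13.46 ± 0.36 (SE, edgeR adjusted p = 4.84e-06). The PBS value of Saa3 rests on 6 counts over the 3 libraries, so the size of its fold is less certain than the SE shows. Ccl2, a monocyte chemoattractant, rose from 9.98 ± 2.61 to 1695 ± 84.9 CPM, and Cxcl5, a neutrophil chemoattractant, from 0.503 ± 0.204 to 650 ± 193 CPM. Slfn2, an interferon-inducible Schlafen gene, rose by a log2 fold change of 4.50 ± 0.14 (SE; edgeR adjusted p = 9.43e-06). Among genes that fell were Fgf18, a fibroblast growth factor, from 46.1 ± 12.3 to 2.75 ± 1.05 CPM (log2 fold change -4.06 ± 0.30; edgeR adjusted p = 0.000253).

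Several genes that rose had no count in any PBS library, so their change is a lower bound against 3 counts over the group. Lcn2, an iron-scavenging lipocalin, was at least 4373-fold higher, and Nos2, the inducible nitric oxide synthase, at least 606-fold higher. Acod1, which makes itaconate, was at least 308-fold higher, Clec4e, a C-type lectin receptor, at least 265-fold, Cxcl3, a chemokine, at least 167-fold, and Tnip3, an NF-kB inhibitor, at least 133-fold. The rmCIRBP libraries differed from each other in some of these genes, with Lcn2 at 215, 67.6 and 731 CPM and Nos2 at 37.2, 4.99 and 98.4 CPM in libraries 1, 2 and 3. The bounds take the pooled rmCIRBP libraries as given and do not cover the spread between them. Without rmCIRBP 3 the bounds were 1830-fold for Lcn2 and 273-fold for Nos2. Without rmCIRBP 2 they were 272-fold for Acod1 and 119-fold for Cxcl3, and without rmCIRBP 1 they were 195-fold for Clec4e and 122-fold for Tnip3. The call of Nos2 (edgeR adjusted p = 0.0240) ended without PBS 2 (0.0750), PBS 3 (0.0715) or rmCIRBP 1 (0.0615).

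The other genes with the largest falls were expressed at low to moderate levels in PBS. Myh8, a skeletal muscle myosin, fell from 2.48 ± 0.937 to 0.0726 ± 0.0723 CPM, and Pkhd1l1, a large membrane protein, from 5.73 ± 3.74 to 0.293 ± 0.195 CPM. Fgf16 fell from 10.7 ± 2.33 to 0.707 ± 0.792 CPM. Stc1, the glycoprotein hormone stanniocalcin 1, fell from 68.4 ± 40.2 to 5.08 ± 3.79 CPM, and Angptl7, an angiopoietin-like secreted protein whose gene lies on the other strand of Mtor, from 39.3 ± 27.3 to 2.71 ± 2.47 CPM. Lgr6, an R-spondin receptor, fell by 4.66 on the log2 scale and Plxdc1 by 4.57. Leaving out rmCIRBP 3 changed the log2 fold change of Fgf16 to -5.34, of Stc1 to -4.46, of Angptl7 to -4.78 and of Pkhd1l1 to -4.91, leaving out PBS 3 gave -3.83 for Lgr6, -3.33 for Plxdc1 and -3.57 for Pkhd1l1, and leaving out rmCIRBP 2 gave -5.74 for Myh8. Tested by edgeR, the calls ended without rmCIRBP 1 for Lgr6 (adjusted p = 0.0538), Stc1 (0.0616), Angptl7 (0.0956) and Plxdc1 (0.0718, log2 fold change -8.07), without PBS 2 for Stc1 (0.0546), Angptl7 (0.0884) and Plxdc1 (0.0764), and without PBS 3 for Angptl7 (0.0924) and Plxdc1 (0.129). The call of Plxdc1 ended also without rmCIRBP 2 (0.0753) or rmCIRBP 3 (0.0853).

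Of 15801 genes tested, 1818 passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05, of which 1065 were higher and 753 lower after rmCIRBP. With upper quartile scaling the split was 925 higher and 1022 lower. Of the 1818, 994 changed by at least 1 on the log2 scale (629 higher, 365 lower), and of the 187 that changed by at least 3, 163 were higher. The groups did not overlap for 1816 of the 1818, and for 34.6% of all genes tested, where chance gives 10%. Without PBS 2, PBS 3 or rmCIRBP 1 the number called was 723, 863 or 742. In these fits 1102, 979 and 1089 of the 1818 calls ended, though all 1818 genes kept their direction. The end of a call without 1 of these libraries was thus common to most called genes and is not particular to a gene named below.

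**Figure D2:**
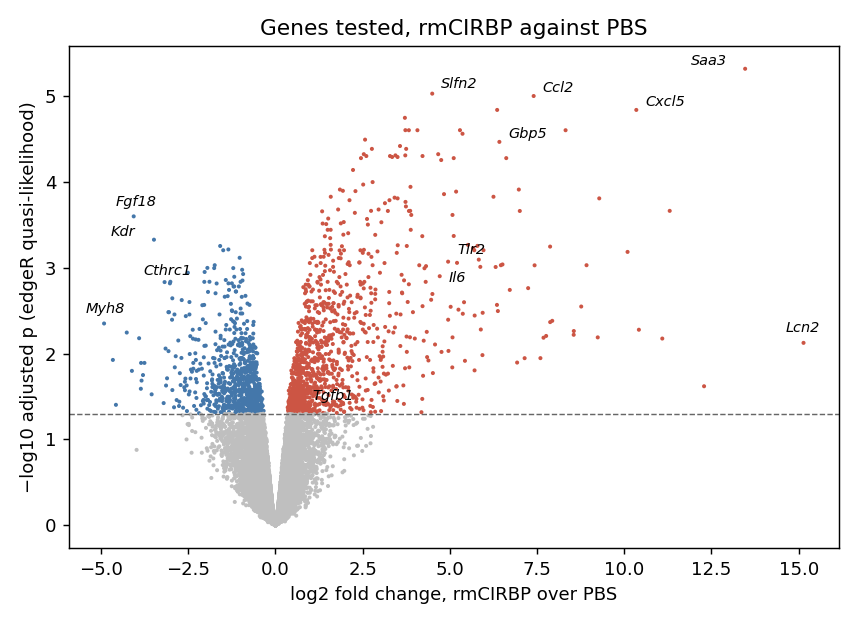
Log2 fold change of rmCIRBP over PBS (horizontal axis) against -log10 of edgeR's adjusted p (vertical axis) for each of 15801 genes, with 1065 called higher in red, 753 called lower in blue and the rest grey; the dashed line is an adjusted p of 0.05. The largest changes are increases, and the fitted value drawn for a gene at 0 in PBS, such as Lcn2, depends on the fit and is no bound.

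The title of the study names fibroblast activation, IL-6, TLR2 and TLR4, and the genes for these were fixed in advance for that reason. Il6, the cytokine gene (chromosome 5, 30013114 to 30019981), rose from 3.12 ± 1.40 to 81.8 ± 42.5 CPM (SD, n = 3 each; log2 fold change 4.71 ± 0.49; edgeR adjusted p = 0.00126). Tlr2, a receptor for bacterial lipoproteins (chromosome 3, 83836272 to 83841767), rose from 2.78 ± 0.958 to 87.0 ± 41.8 CPM (log2 fold change 4.95 ± 0.48; edgeR adjusted p = 0.000851). Tlr4, the lipopolysaccharide receptor, was at 39.6 and 46.8 CPM on average and did not pass (log2 fold change 0.24 ± 0.20; edgeR adjusted p = 0.461). Tgfb1, the profibrotic growth factor, rose from 22.5 ± 1.20 to 40.8 ± 10.4 CPM (edgeR adjusted p = 0.0226), a call that ended without PBS 2 (0.0868), PBS 3 (0.0918) or rmCIRBP 1 (0.0620).

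Of the matrix and contraction genes fixed in advance by name, none passed. Col1a1 and Col3a1, the main fibrillar collagens, had log2 fold changes of -0.25 ± 0.19 and 0.08 ± 0.26 (edgeR adjusted p = 0.429 and 0.875). Fn1, fibronectin, was at 7889 ± 333 and 10493 ± 1633 CPM (log2 fold change 0.41 ± 0.18; edgeR adjusted p = 0.179), and DESeq2 gave an adjusted p of 0.0495. Acta2, the smooth muscle actin of myofibroblasts, was at 1712 ± 880 and 3598 ± 2486 CPM (log2 fold change 1.07 ± 0.55, edgeR adjusted p = 0.239). Its log2 fold change was 0.40 without rmCIRBP 2, which held 6275 CPM against 3155 and 1363 in the other rmCIRBP libraries. Cirbp itself was at 71.1 ± 11.2 and 45.6 ± 8.82 CPM (log2 fold change -0.64 ± 0.17; edgeR adjusted p = 0.0524), and was called lower by DESeq2 (adjusted p = 0.0158) and by edgeR with library size scaling (0.0427).

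**Figure D3:**
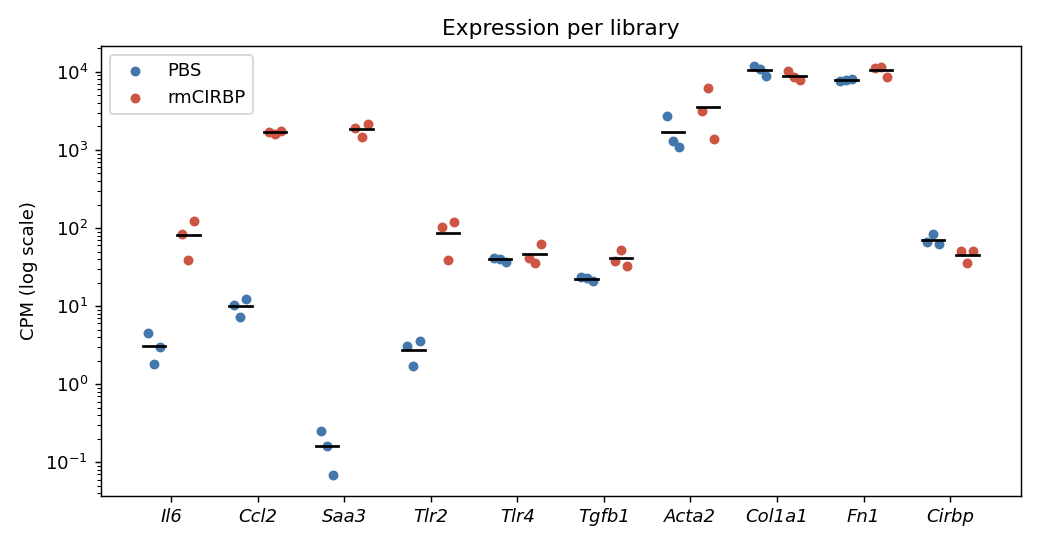
Expression per library in CPM (vertical axis, log scale) of 10 genes, with PBS in blue, rmCIRBP in red and group means as bars. Il6, Ccl2, Saa3, Tlr2, Tgfb1, Fn1 and Cirbp do not overlap between the groups, though Fn1 and Cirbp were not called. Acta2 ranges from 1363 to 6275 CPM among the rmCIRBP libraries.

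Gene lists fixed in advance showed a broad innate immune increase. Of 26 cytokine and chemokine genes, 23 rose and none fell (25 and 0 adjusted over the list alone), with a median log2 fold change of 5.02, among them Ccl7, a monocyte chemoattractant (log2 fold change 6.36), Cxcl5 and Il6. Of 26 genes of the NF-kB pathway and its feedback, 24 rose (26 adjusted over the list alone), including Nfkbia (3.75) and Tnfaip3 (4.67), which restrain NF-kB, and Sod2 (3.57), mitochondrial superoxide dismutase. Camera gave adjusted p = 2.86e-19 for the cytokine list and 6.56e-29 for the NF-kB list, and both held with an estimated correlation (adjusted p = 0.00978 for each). Of the 20 pathway lists, 10 were called, all upward, and these were the only ones of the 10 to hold with an estimated correlation.

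Interferon and antigen presentation genes rose as well. In the type I interferon list 29 of 34 genes rose and none fell (32 and 0 adjusted over the list alone; median log2 fold change 1.60; camera adjusted p = 1.43e-22, and adjusted p = 0.416 with an estimated correlation). Gbp5 (log2 fold change 6.42) and Gbp2 (3.35), guanylate-binding proteins that attack intracellular pathogens, and Ifi47 (2.30), an interferon-inducible GTPase, had the smallest p-values. In the antigen presentation list 16 of 19 genes rose and none fell (17 and 0 adjusted over the list alone; camera adjusted p = 1.55e-14, and adjusted p = 0.382 with an estimated correlation). H2-K1, a class I heavy chain, rose by 2.52 on the log2 scale and Psmb8, an immunoproteasome subunit, by 3.04. H2-Q4 rose by 3.73, overlaps an antisense gene and shares sequence with other H2 genes, as Gbp and Slfn genes do among themselves, so values within these families are uncertain. Of markers of immune cells, those of macrophages did not rise as a set (median log2 fold change -0.41). Of 12 neutrophil markers listed, only 3 passed the filter, and all 3 rose (median 3.63). Without a filter on low counts 6 were called upward as a set (camera adjusted p = 2.11e-07). RNA of whole cultures does not show which cells made these transcripts, so the rise does not show that neutrophils were present.

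In the list of IL-6 family receptors and STAT3 targets, a theme the title names, 12 of 21 genes rose and none fell (13 and 0 adjusted over the list alone; camera adjusted p = 1.08e-08, and adjusted p = 0.452 with an estimated correlation). Saa3 and Hp, haptoglobin (log2 fold change 6.62), are acute-phase genes, and Jak2, the kinase of cytokine receptors, rose by 1.87. In the list of TLR signalling components, also named in the title, 5 of 16 genes rose and none fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.00539, and adjusted p = 0.416 with an estimated correlation). These were Lbp, which presents lipopolysaccharide (log2 fold change 5.70), Tlr2, Tlr3, the receptor for double-stranded RNA (1.84), and, named after their values were seen, Cd14 (2.86), a lipopolysaccharide co-receptor, and the adaptor Myd88 (0.62). With edgeR, Myd88 was no longer called without PBS 2 (adjusted p = 0.0858), PBS 3 (0.0766), rmCIRBP 1 (0.0871) or rmCIRBP 3 (0.0693).

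**Figure D4:**
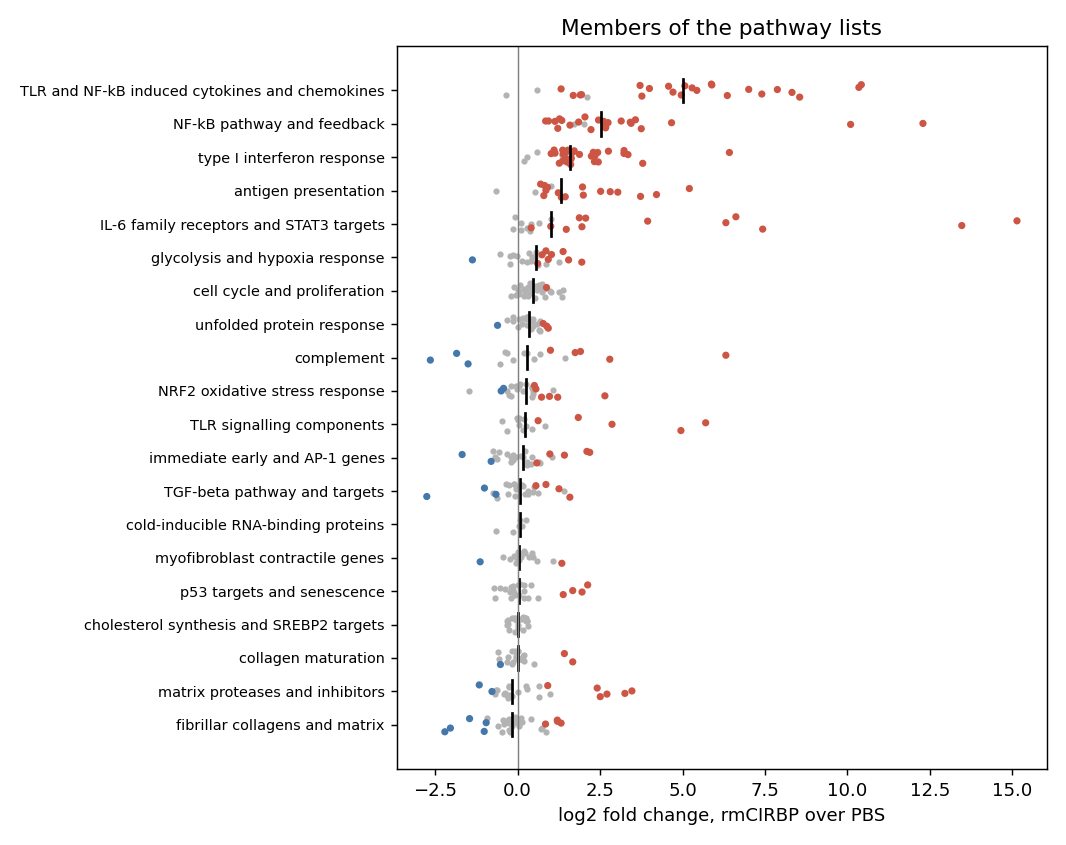
Log2 fold change of rmCIRBP over PBS (horizontal axis) for each tested member of the 20 pathway lists (vertical axis), with called increases in red, called decreases in blue, uncalled genes in grey and the median of each list as a black bar. The medians are 5.02 for the cytokine list, 2.53 for the NF-kB list and 1.60 for the interferon list.

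Matrix genes moved in both directions. Of 32 fibrillar collagen and matrix genes, 4 rose and 5 fell (4 and 6 adjusted over the list alone; median log2 fold change -0.16; camera adjusted p = 0.164), while fry, which tests whether the genes move one way on balance, gave adjusted p = 0.0257 for a decrease. Mfap5, a microfibril protein, fell from 204 ± 8.54 to 105 ± 3.52 CPM, Cthrc1, a secreted collagen-related protein, from 80.2 ± 18.0 to 19.5 ± 4.48 CPM, and Col11a1 by 1.01 on the log2 scale. Outside the rule for named genes, and chosen after their values were seen, Eln, elastin (log2 fold change -2.20), and Fbln5, an elastic fibre protein (-1.46), fell, whereas Vcan (1.20), Dcn (1.21), both proteoglycans, Col5a3 (1.32) and Col12a1 (0.85) rose. In edgeR's test, leaving out PBS 2 ended the calls of Fbln5 (adjusted p = 0.0513), Dcn (0.0846), Col5a3 (0.0616) and Col12a1 (0.143). Leaving out rmCIRBP 1 ended those of Dcn (0.0771), Col5a3 (0.0512) and Col12a1 (0.114), PBS 3 those of Col5a3 (0.0853) and Col12a1 (0.114), rmCIRBP 3 that of Dcn (0.0589), and PBS 1 (0.0515) or rmCIRBP 2 (0.0860) that of Col12a1.

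Of 25 matrix proteases and inhibitors, 6 rose and 2 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.669; upward, with a median of -0.16 but a mean of 0.48). Mmp3, stromelysin, rose from 42.6 ± 16.7 to 471 ± 261 CPM, Mmp13, a collagenase, from 4.45 ± 1.05 to 23.8 ± 4.50 CPM, and Timp1, a protease inhibitor, from 101 ± 18.5 to 576 ± 156 CPM. Named after their values were seen, Mmp11 (log2 fold change -0.78) and Plat, tissue plasminogen activator (-1.16), fell. Both calls ended in edgeR's test without PBS 2 (adjusted p = 0.0686 and 0.0952), PBS 3 (0.0568 and 0.0922) or rmCIRBP 1 (0.0582 and 0.0757).

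Of 23 collagen maturation genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.929). Adamts14, a procollagen protease, rose by 1.42 on the log2 scale, P4ha2, a prolyl hydroxylase, rose by 1.67, and Plod2, a lysyl hydroxylase, fell by 0.52. Of 26 genes of the TGF-beta pathway, 4 rose and 3 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.715). Id2, a transcriptional inhibitor (1.58), Ltbp2, a latent TGF-beta binding protein homologue (1.26), Tgfb1 and Itgav (0.56) rose, and Itgb5 (-0.66), Pmepa1 (-1.01) and Tgfbi (-2.75) fell, with Itgav, Pmepa1 and Tgfbi named after their values were seen. Tested by edgeR, leaving out rmCIRBP 1 ended the calls of Plod2 (adjusted p = 0.147), Itgb5 (0.0583), Pmepa1 (0.0515), Itgav (0.0582), Tgfbi (0.0912) and Tgfb1 (0.0620). Plod2, Tgfb1, Itgav and Tgfbi were also lost without PBS 2 (0.114, 0.0868, 0.149 and 0.115) or PBS 3 (0.143, 0.0918, 0.0767 and 0.124), Plod2, Itgav and Tgfbi without rmCIRBP 2 (0.0809, 0.0754 and 0.0703), Itgav and Tgfbi without rmCIRBP 3 (0.0881 and 0.0727), and Itgav without PBS 1 (0.0731).

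Of 19 myofibroblast contractile genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.929, downward, though the median log2 fold change was 0.04 and the mean 0.15). Myh10, nonmuscle myosin IIB, fell from 537 ± 52.7 to 244 ± 22.9 CPM. Tagln2, transgelin 2, rose from 119 ± 29.1 to 301 ± 88.4 CPM, a call that ended in edgeR's test without PBS 2 (adjusted p = 0.0686), PBS 3 (0.0564) or rmCIRBP 1 (0.0539). All 19 genes were higher in rmCIRBP 2 than in the mean of the other rmCIRBP libraries, with a median log2 ratio of 0.99. Among the PBS libraries Acta2 was highest in PBS 1 (2721 CPM against 1312 and 1103). Without rmCIRBP 2 alone the list was called downward (camera adjusted p = 0.0118), but not without PBS 1 and rmCIRBP 2 together (0.255), and without rmCIRBP 3 it leaned upward (0.0877), so no direction is given for it.

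Of 26 glycolysis and hypoxia genes, 8 rose and 1 fell (11 and 1 adjusted over the list alone; median log2 fold change 0.54; camera adjusted p = 0.000309, and adjusted p = 0.605 with an estimated correlation). Pfkl, the liver phosphofructokinase, rose by 1.38, Ldha, lactate dehydrogenase A, by 1.03 and Ndrg1, a hypoxia-induced gene, by 0.61, while Car9, a hypoxia-induced carbonic anhydrase named after its values were seen, fell by 1.37. Of 24 unfolded protein response genes, 3 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.00166, and adjusted p = 0.605 with an estimated correlation). The sensor Ern1 (0.93) and the chaperones Hyou1 (0.88) and Hspa5 (0.78, named after its values were seen) rose, and Ddit3, a proapoptotic transcription factor whose gene overlaps Mars1, fell by 0.61. With edgeR, leaving out PBS 3 ended the calls of Ldha, Ndrg1, Car9, Hyou1, Hspa5 and Ddit3 (adjusted p = 0.0804, 0.0630, 0.102, 0.0816, 0.147 and 0.125), and PBS 2 those of all of these except Ndrg1 (0.0938, 0.108, 0.0805, 0.152 and 0.128). Leaving out rmCIRBP 1 ended those of Ldha, Ndrg1, Car9, Hspa5 and Ddit3 (0.0673, 0.0667, 0.102, 0.0776 and 0.128), rmCIRBP 3 those of Car9, Hspa5 and Ddit3 (0.0778, 0.0777 and 0.0899), rmCIRBP 2 that of Hspa5 (0.0832) and PBS 1 that of Car9 (0.0519).

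Of 25 NRF2 oxidative stress genes, 6 rose and 2 fell (12 and 3 adjusted over the list alone; camera adjusted p = 0.0397, and adjusted p = 0.494 with an estimated correlation). Gsr, glutathione reductase (log2 fold change 0.97), Gclc, which makes glutathione's precursor (0.73), and Prdx6, a peroxiredoxin (1.22), rose, and Gpx1 (-0.50) and Sod1 (-0.43), antioxidant enzymes named after their values were seen, fell. The list's call ended without PBS 1 (camera adjusted p = 0.0575), PBS 2 (0.0972) or rmCIRBP 1 (0.0785). In edgeR's test Prdx6, Gpx1 and Sod1 were not called without PBS 2 (adjusted p = 0.0746, 0.0598 and 0.128) or PBS 3 (0.0552, 0.0904 and 0.143), Gpx1 and Sod1 without rmCIRBP 1 (0.109 and 0.151), Sod1 without rmCIRBP 2 (0.0917) and Gpx1 without rmCIRBP 3 (0.0652).

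Of 35 cell cycle genes, 1 rose and none fell (0 and 0 adjusted over the list alone), with a median log2 fold change of 0.48 (camera adjusted p = 0.000256, and adjusted p = 0.773 with an estimated correlation). It was Tyms, thymidylate synthase (0.85), whose call ended in edgeR's test without PBS 2 (adjusted p = 0.120), PBS 3 (0.117), rmCIRBP 1 (0.107) or rmCIRBP 2 (0.0759). Mcm3, a replicative helicase subunit, had a log2 fold change of 1.37 (adjusted p = 0.0687) and Pcna, the replication clamp, of 0.82 (adjusted p = 0.0918) in edgeR's test. DESeq2 called both (0.00652 and 0.0315), as did edgeR without PBS 1 (0.0346 and 0.0225), and without rmCIRBP 3 edgeR called Mcm3 (0.0439). Of 23 cholesterol synthesis genes 0 passed by edgeR, DESeq2 or limma voom (0 at an unadjusted edgeR p under 0.05; 0 adjusted over the list alone), Mvk, mevalonate kinase, having a log2 fold change of -0.31, and the list was not called (camera adjusted p = 0.922) except upward without PBS 1 (0.00631). Of 6 cold-inducible RNA-binding protein genes 0 passed by edgeR or limma voom and 1 by DESeq2, with 1 at an unadjusted edgeR p under 0.05 (0 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.929). With library size or upper quartile scaling edgeR called 1 of the 6 lower.

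Of 24 p53 and senescence genes, 4 rose and none fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.310). Fas, a death receptor (log2 fold change 2.12), Plk2, a polo-like kinase (1.38), Gdf15, a stress cytokine (1.67), and, named after its values were seen, Igfbp3 (1.95) rose. Of 17 complement genes, 5 rose and 3 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.465), and limma voom called 5 of the 17. C3, the central component, rose from 77.7 ± 21.3 to 6177 ± 4166 CPM, with 6116, 2042 and 10374 CPM in rmCIRBP libraries 1, 2 and 3, and its log2 fold change of 6.31 was 5.72 without rmCIRBP 3. C2 (1.91; it overlaps Zbtb12) and, named after their values were seen, C1ra (1.75), Cfb (2.80) and C4b (1.00) rose, and Masp1 (-1.50; it overlaps the interferon-inducible Rtp4 on the other strand), C1qa (-2.64) and C5ar1 (-1.85), the last 2 named after their values were seen, fell. Of these 7, all but Masp1 were not called in edgeR's test without PBS 2 (adjusted p from 0.0513 to 0.163) or PBS 3 (0.0667 to 0.155), and none of the 7 without rmCIRBP 1 (0.0580 to 0.139). The fold of Cfb was 3.59 on the log2 scale without PBS 1, and that of C1qa was -3.85 without rmCIRBP 2. C1ra, C1qa, C4b and C5ar1 were lost also without PBS 1 (0.0825, 0.0577, 0.0882 and 0.0536), C1ra, Cfb, C1qa, C4b and C5ar1 without rmCIRBP 3 (0.0713, 0.0841, 0.0699, 0.0851 and 0.0909) and C5ar1 without rmCIRBP 2 (0.117).

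Of 27 immediate early and AP-1 genes, 5 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.624). Ier3, an early response gene (2.10), and the AP-1 subunits Fosl2 (0.98) and Fosl1 (2.19; it overlaps Ccdc85b) rose, as did Myc (1.42) and Ier5 (0.58), while the nuclear receptors Nr4a2 (-0.80) and Nr4a3 (-1.68) fell, these last 4 named after their values were seen. Tested by edgeR, Myc, Ier5, Nr4a2 and Nr4a3 were not called without PBS 2 (adjusted p = 0.0908, 0.0827, 0.0658 and 0.132) or PBS 3 (0.0729, 0.0789, 0.0703 and 0.0939), Ier5, Nr4a2 and Nr4a3 without rmCIRBP 1 (0.0772, 0.0666 and 0.134), Ier5 and Nr4a2 without rmCIRBP 3 (0.0575 and 0.0614) and Nr4a3 without rmCIRBP 2 (0.0838). Without rmCIRBP 2 the immediate early list (camera adjusted p = 0.00166), the complement list (0.0223) and the p53 list (0.0187) were called upward. Without PBS 1 and rmCIRBP 2 together, a fit chosen after the results were seen, the immediate early (0.00611) and complement (0.0244) lists were called and the p53 list was not (0.0995).

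Of 7 cell type and quality lists 0 were called by camera, with either correlation, or by fry, and at an unadjusted p under 0.05 camera called 0 and fry 1 (endothelium, 0.0180). Lyz2, the macrophage lysozyme, was at 109 ± 15.6 and 74.4 ± 26.0 CPM and Csf1r, the macrophage colony-stimulating factor receptor, at 9.86 ± 1.84 and 13.3 ± 1.29 CPM, neither called, though Csf1r overlaps Hmgxb3 on the other strand. Of 18 macrophage and monocyte markers 3 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.844, downward, with a median of -0.41 and a mean of 0.16). Named after their values were seen, Marco (log2 fold change 5.52), Adgre1 (2.46) and Siglecf (3.03) rose, and Mrc1 (-1.65), C1qa (-2.64) and C1qb (-1.75) fell. Marco and Adgre1 were called in each leave-one-out fit, Siglecf in none of the 6 (edgeR adjusted p from 0.0512 without PBS 2, where its log2 fold change was 4.61, to 0.172 without PBS 3). With edgeR, Mrc1, C1qa and C1qb were not called without PBS 2 (adjusted p = 0.121, 0.156 and 0.146), PBS 3 (0.0946, 0.0899 and 0.0600), rmCIRBP 1 (0.0977, 0.139 and 0.104) or rmCIRBP 3 (0.0619, 0.0699 and 0.0746), nor C1qa and C1qb without PBS 1 (0.0577 and 0.0554), and without rmCIRBP 2 the log2 fold change of C1qa was -3.85.

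Of 7 endothelial markers 0 rose and 2 fell (0 and 2 adjusted over the list alone; camera adjusted p = 0.818). Kdr, a VEGF receptor, fell from 13.9 ± 2.71 to 1.24 ± 0.395 CPM (edgeR adjusted p = 0.000472), Tek, named after its values were seen, by 0.99 on the log2 scale, and Flt1 was at 20.1 ± 6.91 and 28.6 ± 5.34 CPM. Of 18 lung fibroblast markers 1 rose and 3 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.589), and 6 of the 18 are also in other lists. Col1a2 was at 8788 ± 607 and 6802 ± 813 CPM. Named after their values were seen, Scara5 (-2.96), Thy1, a surface glycoprotein (-1.21), and Vim, vimentin (-0.88), fell, and Dcn (1.21) rose. In edgeR's test Tek was not called without any 1 of PBS 2 (adjusted p = 0.0997), PBS 3 (0.0970), rmCIRBP 1 (0.0524), rmCIRBP 2 (0.0576) or rmCIRBP 3 (0.0663), nor Dcn without PBS 2 (0.0846), rmCIRBP 1 (0.0771) or rmCIRBP 3 (0.0589).

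Of 14 pericyte and smooth muscle markers 1 rose and 1 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.818), namely Ndufa4l2 (0.98) and Cspg4 (-2.05), named after their values were seen. Myh11 was at 274 ± 150 and 314 ± 310 CPM and Actg2 at 200 ± 134 and 297 ± 309 CPM. Their log2 fold changes of 0.19 and 0.57 were -0.97 and -0.68 without rmCIRBP 2, and that of Actg2 was 1.29 without PBS 1. Of 6 mesothelial markers 2 rose and 1 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.818). Aldh1a2, which makes retinoic acid, rose from 78.0 ± 23.5 to 213 ± 29.5 CPM, Rspo1 rose (2.32) and Upk3b fell (-2.30), the last pair named after their values were seen, and Msln, mesothelin, was at 5.32 ± 2.00 and 3.29 ± 1.74 CPM. Tested by edgeR, Ndufa4l2, Rspo1 and Upk3b were not called without PBS 2 (adjusted p = 0.0885, 0.0947 and 0.0928), PBS 3 (0.0915, 0.129 and 0.0636), rmCIRBP 1 (0.0569, 0.0764 and 0.0602) or rmCIRBP 3 (0.0664, 0.0620 and 0.0678). Cspg4 was not called without PBS 2 (0.0575) or rmCIRBP 3 (0.0504), nor Rspo1 and Upk3b without PBS 1 (0.0664 and 0.0596), and the log2 fold change of Rspo1 was 1.65 without rmCIRBP 3 and that of Upk3b -3.01 without rmCIRBP 2.

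Fewer than 5 genes were measured of the neutrophil, epithelial, lymphocyte and erythroid lists, which were not tested as sets. Without a filter on low counts 6 neutrophil markers could be tested, and camera called them upward (adjusted p = 2.11e-07). Of 12 neutrophil markers listed, 3 passed the filter and all of these rose. Mmp8, a collagenase, went from 1.61 ± 0.918 to 19.8 ± 6.74 CPM, Mmp9, a gelatinase also in the protease list, from 0.602 ± 0.204 to 4.04 ± 0.872 CPM, and Camp, an antimicrobial peptide named after its values were seen, from 0 counts to 2.02 ± 0.710 CPM. Of 4 epithelial markers 0 passed by edgeR, DESeq2 or limma voom (0 at an unadjusted edgeR p under 0.05), Ager being at 3.55 ± 1.41 and 4.69 ± 2.06 CPM and Krt19 at 3.09 ± 1.11 and 2.37 ± 2.27 CPM, and no lymphocyte or erythroid marker was abundant enough to be tested.

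Mitochondrial genes took 1.31 ± 0.0883% and 1.31 ± 0.110% of the counts (SD, n = 3; exact permutation p = 1), and of 10 such genes 0 passed by edgeR or limma voom and 1 by DESeq2, with 1 at an unadjusted edgeR p under 0.05 (camera adjusted p = 0.818). Of 12 heat shock and dissociation genes 0 rose and 1 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.963). This was Hspb1 (log2 fold change -0.55), named after its values were seen, whose call ended in edgeR's test without PBS 1 (adjusted p = 0.0756), PBS 2 (0.113), PBS 3 (0.0841), rmCIRBP 1 (0.123) or rmCIRBP 3 (0.0833). Ribosomal RNA took 0.124 ± 0.00811% of the counts in PBS and 0.0659 ± 0.00523% in rmCIRBP (SD, n = 3; exact permutation p = 0.1, the smallest possible). Noncoding genes and pseudogenes together took 3.92 ± 0.204% and 3.54 ± 0.0404% (exact permutation p = 0.1), and ribosomal protein genes 3.01 ± 0.177% and 2.67 ± 0.248% (exact permutation p = 0.2).

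Gene Ontology terms carried by the deposited table gave a similar picture. Of 2496 terms, 146 were called by camera, 136 upward and 10 downward, and 0 by camera with an estimated correlation (adjusted p = 0.888 for each of the terms named here), where 118 had an unadjusted p under 0.05. In the term cellular response to interferon-beta 21 of 39 genes rose (camera adjusted p = 1.32e-12), in defense response to virus 53 of 120, and in chemokine activity 16 of 24. In cellular response to lipopolysaccharide 33 of 90 genes rose and 3 fell (camera adjusted p = 8.45e-06). In ribosome biogenesis 10 of 60 genes rose and none fell (camera adjusted p = 1.43e-05). Downward terms included embryonic skeletal system development, where 5 of 27 genes fell (camera adjusted p = 0.00332), and axoneme, where 5 of 54 fell (0.0113).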

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

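The fits without PBS 1 and rmCIRBP 2 together, all alternatives of the principal components, and those of the Gene Ontology terms other than the estimated correlation were chosen after the results were seen. All 1818 genes called kept their direction in each alternative where they were tested. With a mean CPM of at least 1 these were 1773 of them, and among protein-coding genes alone 1617. The groups did not overlap for 1816 of the 1818, so leaving out a library could hardly change a direction. The number called was 1823 with DESeq2 size factors, 1863 with library size, 1947 with upper quartile factors, 1801 with a mean CPM of at least 1, 2607 without a filter, 2618 with DESeq2, 1738 with limma voom, 1786 with a robust fit and 1725 among protein-coding genes alone. Leaving out 1 library gave 723 (without PBS 2) to 2144 (without PBS 1) genes, of which 716 and 1517 were among the 1818. Without PBS 1 and rmCIRBP 2 together 2802 were called, 1643 of them among the 1818, and the cause was not tested. At an adjusted p of 0.01 the number was 608, at 0.1 it was 3066, and with a log2 fold change of at least 1 it was 994, which follows from the thresholds. Upper quartile factors turned the split to 925 higher and 1022 lower, and moved the median log2 fold change of all genes from -0.01 to -0.07.

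Camera called 2 pathway lists and 0 terms with an estimated correlation, against 10 and 146 with the preset one. The estimated correlation was 0.75 in the interferon list, but -0.03 in the term chemokine activity, which was lost as well. Camera's unadjusted p for that term was 0.00157 with the estimated correlation and 5.54e-12 with the preset one. Correlation alone thus does not account for the difference, whose cause was not isolated. A call absent with the estimated correlation does not show that a list or term was unchanged. Leaving out 1 library gave 9 (without PBS 2 or rmCIRBP 1) to 14 lists (without rmCIRBP 2) and 140 (without PBS 3) to 164 terms (without PBS 1). Fry called 8 lists, and not the cell cycle (adjusted p = 0.351), glycolysis (0.141) or unfolded protein (0.126) lists. Of the cell type and quality lists 1 was called upward without a filter, the neutrophil list (camera adjusted p = 2.11e-07), which has 3 members with the filter, too few to test, and 6 without it, and leaving out 1 library gave 0 throughout. The first component held 45.8% of the variance without a filter, which adds genes of low count, and 60.1% (without PBS 2) to 66.2% (without rmCIRBP 3) with 1 library left out. No gene or list that was called reversed in any alternative.

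The labels do not say whether the replicate numbers pair the samples. The deviations of same-numbered libraries from their group means correlated at -0.11, -0.17 and 0.25. With 3 libraries per group such values depend on each other, so they cannot exclude a shared animal or day. With the number as a replicate block 1258 genes were called (792 higher, 466 lower), 1195 of them among the 1818, with 10 pathway lists, 0 cell type and quality lists and 151 terms. Depth limits what can be said of genes near 0.248 CPM, the level of 3 counts in the shallowest library, such as Myh8 after rmCIRBP.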

Other observations

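The tests of smooth muscle markers, of depth and mitochondrial share and of macrophage markers, and all gene families given here, were chosen after the results were seen. Interferon-inducible and protease inhibitor families rose throughout. All 7 protein-coding guanylate-binding genes tested rose, from Gbp7 (log2 fold change 1.63) to Gbp5 (6.42), as did all 4 protein-coding Schlafen genes tested, from Slfn9 (1.42) to Slfn2 (4.50). The 4 protein-coding Serpina3 genes tested, which encode serine protease inhibitors of the acute phase, also rose, among them Serpina3g from 3.21 ± 0.418 to 108 ± 45.0 CPM (SD, n = 3; edgeR adjusted p = 0.000243). These counts hold with library size, DESeq2 and upper quartile scaling, and members of each family share sequence. Of 8 ligands of the TNF family 4 rose and none fell, namely Tnfsf18, Tnfsf13b, which keeps B cells alive, Tnfsf11, which drives osteoclast formation, and Tnfsf8. Tnfsf13b rose from 6.40 ± 0.0784 to 38.6 ± 18.6 CPM (SD, n = 3). Tnfsf18 had a log2 fold change of 5.37, and 4.44 without rmCIRBP 2. Tnfsf11 had 4.34, and 5.25 without PBS 1 or 3.73 without PBS 3. Tnfsf8 had 2.87, and 4.12 without PBS 1, and its call ended in edgeR's test without PBS 2 (adjusted p = 0.0859), PBS 3 (0.0840) or rmCIRBP 1 (0.0682).

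Some positional and adhesion genes fell, though most members of these families were not called and no set test was made of the families as defined here. The Gene Ontology term integrin complex, where 1 of 14 genes rose and 6 fell, was not called (camera adjusted p = 0.104). Of 16 Hox genes, which set position along the body axis, 5 fell and none rose, with 6 lower under upper quartile scaling. They were Hoxb8 (31.6 ± 3.14 to 15.8 ± 1.04 CPM), Hoxb3 (log2 fold change -0.85), Hoxb5 (-0.98), Hoxa5 (-0.59) and Hoxb6 (-0.63). By edgeR, Hoxa5 and Hoxb6 were not called without PBS 3 (adjusted p = 0.0557 and 0.0540) or rmCIRBP 1 (0.0546 and 0.0644). Of 18 integrin genes, leaving aside Itga2b, Itgal and Itgax, 1 rose (Itgav) and 5 fell, with 0 and 6 under upper quartile scaling. Itga11, a collagen receptor, fell by 2.46 on the log2 scale and Itgb3 by 1.18, and both were called whichever library was left out. The others that fell were Itgb5, Itga7 and Itga3. In edgeR's test Itgb5, Itga7, Itga3 and Itgav were not called without rmCIRBP 1 (adjusted p = 0.0583, 0.0643, 0.143 and 0.0582), and Itga7, Itga3 and Itgav were not called without PBS 2 (0.0642, 0.0783 and 0.149). Itga3 and Itgav were lost without each other library as well (0.0572 to 0.124). Of 13 fibroblast growth factors 2 rose and 3 fell. Fgf7, a mitogen of epithelial cells, rose from 108 ± 5.01 to 247 ± 67.3 CPM, and Fgf23, a phosphate-regulating hormone, from 0 counts to 2.19 ± 0.615 CPM. Fgf18 (log2 fold change -4.06), Fgf16 (-3.91, and -5.34 without rmCIRBP 3) and Fgf5 (-3.13, and -4.05 without rmCIRBP 3) fell. Fgf5 was not called by edgeR without PBS 2 (adjusted p = 0.0608), PBS 3 (0.0527), rmCIRBP 1 (0.0943) or rmCIRBP 2 (0.0576).

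The library rmCIRBP 2 lay apart from the other rmCIRBP libraries on the second component, with higher contractile genes (median log2 ratio 0.99) and lower Nos2 (4.99 CPM against 37.2 and 98.4), and some contractile genes were also higher in PBS 1 than in PBS 2 and PBS 3 (Acta2 2721 CPM against 1312 and 1103, Actg2 355 against 129 and 116), though Myh10, Palld and Synpo2 were not. RNA of unstimulated cells would lower all 86 strongly induced genes by 1 factor. Their median log2 ratio in rmCIRBP 2, against the mean of rmCIRBP 1 and rmCIRBP 3, was -0.63, and 21 of the 86 were higher. Yet 27.9% of them lay over 1 log2 unit from that median, against 9.30% for rmCIRBP 1 over rmCIRBP 3. Ccl20 was higher (257 CPM against 75.7 and 89.8). A shared factor alone would not give this spread, though some dilution is not excluded. Of the total count and mitochondrial share of rmCIRBP 2, 0 lay outside the range of the other 5 libraries, which argues against lower depth or a different mitochondrial share. Smooth muscle or pericyte markers outside the contractile list had a median log2 ratio of 0.29, with quartiles of -0.46 and 1.37, so a higher share of these cells cannot be told apart from a more contractile state of the fibroblasts. What set rmCIRBP 2 apart, and whether PBS 1 shares its cause, stays open.

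Of 2962 noncoding genes and pseudogenes tested, 201 were called, and many lay beside a called coding gene. Among called ones inside a coding gene on the opposite strand, 82% (41 of 50) had a host called in the same direction, against 7.70% (54 of 701) of uncalled ones (Fisher's exact p = 2.13e-32). Within 5 kb of a coding gene the shares were 74.7% (112 of 150) and 9.53% (202 of 2120). The pattern is what reads of the coding gene counted to its neighbour would give, and such reads may account for part of these calls. Transcription of both genes together would give it too, and without a stated strand setting it stays open.

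A higher share of macrophages in the rmCIRBP cultures could raise cytokine and interferon genes. The upper quartile of the log2 fold changes of 18 macrophage markers was 0.85, below the interferon list's median of 1.60. Lyz2, the most abundant, was at 109 ± 15.6 and 74.4 ± 26.0 CPM, and Csf1r at 9.86 ± 1.84 and 13.3 ± 1.29 CPM, neither called. Of the 18 markers 3 rose and 3 fell. These values argue only against a higher share of macrophages whose marker expression was unchanged by treatment. They cannot exclude a higher share of macrophages whose markers changed with treatment. Nor do they bear on a response of macrophages present in both groups, since RNA of whole cultures does not show which cells made a transcript. Of the 18 markers, 2 are also in other lists. Marco and Adgre1, which rose, stayed below 15 CPM in each library. The 6 libraries hold no arm with a bacterial ligand or inactivated protein, so the response to the protein itself was not separated from that to anything carried with it.

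The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes, 1 split, the real one, gave as many as 1818, and the highest other gave 0. For terms 1 split, the real one, gave as many as 146, and the highest other gave 103. For pathway lists 4 splits gave at least the real 10, and the highest other gave 11. For cell type and quality lists all 10 splits gave at least the real 0, and the highest other gave 3. Each other split mixes treated and PBS libraries unevenly, so part of the treatment difference remains between its groups. That difference also widens the spread within its groups, which lowers the number of genes called. The lists and terms that camera called along these splits may hold that part or other differences between the libraries, and the splits cannot tell which. Lists whose call ended with an estimated correlation stay uncertain.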
